A study of Mus musculus with 19 samples.

How the data were processed

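Left ventricular RNA was measured by RNA sequencing in 12 mouse libraries, 3 in each of 4 groups given by the labels: control and JP2NT-OE hearts, each at baseline and 3 weeks after transverse aortic banding. Polyadenylated RNA was sequenced from stranded libraries, per the labels' protocols. The series has 19 samples. Its 7 chromatin immunoprecipitation samples were not analysed here.

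The submitters' processing notes name FastQC 0.11.3, cutadapt 1.8.1, kallisto 0.42.5, Bowtie2 2.2.5 and MACS 1.4.2, and the genome build mm10, without giving the role or order of each. Each deposited table lists 96626 Ensembl mouse transcript IDs with a length, an effective length, an estimated count and a TPM value, per the file headers. The estimated counts deposited by the authors need not be whole, because reads that match several transcripts were divided among them. The TPM values deposited by the authors (abundances corrected for transcript length) sum to 1000000 in each library, and therefore carry no depth. The effective lengths, in bases per the file headers, depend on the fragment length of the library. The transcript annotation and its release are not given in the sources used here.

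The tables give transcript IDs only and do not pair them with gene names. None of the IDs was found in the table of gene names used here (0 matched), so counts could not be summed per gene as had been planned. The tests were run on transcripts instead, which was the fallback fixed before the data were examined. For the same reason 27 gene lists fixed beforehand, the check of the transgene's own gene in every library, the check of sex-specific genes and the alternative without mitochondrially encoded genes were not run. A gene whose reads moved from one transcript to another appears here as a change in both, and reads shared between similar transcripts were divided by the authors' software.

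Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Transcripts were filtered with filterByExpr by group, which left 43256 and removed 53370. Libraries were scaled with TMM factors, which assume that most transcripts do not change, and 1 mean per group was fitted over all 12 libraries, which left 8 residual degrees of freedom. Each of 5 contrasts was tested with the quasi-likelihood test: banding in control, banding in JP2NT-OE, genotype at baseline, genotype after banding, and the difference between the banding effects of both genotypes (the interaction). A transcript was called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken from the fold change and its test statistic. Abundances are TMM-scaled CPM (counts divided by the scaled library total), and their log2 values used a prior count of 2.

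The rule for named items, fixed before the data were examined, took those with the largest log2 fold changes in each direction among called transcripts with a mean of at least 1 on the log2 CPM scale and no overlap between the groups compared. Because IDs could not be paired with gene names, only 4 of those IDs are printed: the first in each direction for banding in control, the first for genotype at baseline and the first for the interaction. This restriction was chosen after the values were seen. The remaining calls are described by number, direction, abundance and length.

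The size of the response to banding was estimated across 18617 transcripts with a mean of at least 1 on the log2 CPM scale. It is the SD, across transcripts, of the log2 effect, obtained from products of differences between separate libraries, so that the spread between libraries does not add to it. The genotypes were compared with an exact two-sided permutation test that exchanged genotype within the baseline and within the banded libraries over 400 assignments. This estimate was chosen after the numbers of calls were seen. In a further comparison chosen after the data were seen, the 500 transcripts ranked first in each direction by limma 3.58.1 in 4 control libraries were read in the 2 control libraries left out and in JP2NT-OE, for all 9 choices of the libraries left out. The reverse selection, in 4 JP2NT-OE libraries, was made in the same way. A first version that took only transcripts past the threshold in those 4 libraries picked too few to summarise.

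The methods were tested on simulated counts drawn from the control baseline means and from the spread and sizes of these libraries. For banding in control, 200 of 43256 transcripts were changed. That is far fewer than the 3722 called in the real comparison. Recovery at an adjusted p depends on this number, so the rates do not carry over directly. Of the changed transcripts with at least 5 CPM, the test recovered 21.1% at 1.5-fold (4 of 19), 85.7% at 2-fold (18 of 21) and 82.4% at 4-fold (14 of 17). Over all abundances it recovered 5.97%, 26.9% and 39.4%, with 0 false calls. The estimate of response size returned 0.502 for a simulated ratio of 0.5 and 0.998 for a ratio of 1.

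Totals ran from 37662212 to 53097801 estimated counts per library. A total of 3 counts over the libraries of a group corresponds to between 0.0211 and 0.0253 CPM, which limits the lowest abundance that can be told from 0. This covers counting error only. Alternatives fixed beforehand were DESeq2 1.42.0, RLE factors, other filters on low counts, fits of only the groups compared, limma on log2(TPM + 1) and log2(TPM + 0.1), effective-length offsets, the replicate number as a block, and leaving out each replicate. Those chosen after seeing the data were library totals without TMM factors, leaving out the 20 most abundant transcripts, using only transcripts with whole counts in all 12 libraries (within 0.01), and thinning each library to the shallowest total.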

Results

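The response of the left ventricle to pressure overload was measured in mice with and without a cardiac transgene. JP2NT-OE mice express an HA-tagged N-terminal fragment of junctophilin-2 under the α-MHC promoter, which is active in heart muscle cells. Junctophilin-2 holds the transverse tubules of these cells close to the sarcoplasmic reticulum. Littermates without the transgene served as controls. Transverse aortic banding (TAB), an operation that narrows the aorta and raises the load on the left ventricle, was performed in males at 9 weeks of age, and hearts were taken 3 weeks later. Baseline hearts came from littermates without surgery, also at 12 weeks of age. There was no group with a sham operation, so the load cannot be told apart from the surgery itself. Below, a change with banding means a difference between banded and unoperated hearts. Each of the 4 groups had 3 RNA-seq libraries. The labels number the replicates without stating that each was a separate mouse, so the p-values measure the spread between these libraries.

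Total estimated counts ran from 37662212 to 44173258 in control baseline, from 38255668 to 45350628 in control TAB, from 41844570 to 44634328 in JP2NT-OE baseline and from 40615344 to 53097801 in JP2NT-OE TAB libraries. The first principal component of log2 CPM held 16.2% of the variance and separated banded from baseline libraries. Control libraries lay between -80.0 and -58.4 at baseline and between 86.6 and 94.9 after TAB. JP2NT-OE libraries lay between -57.7 and -54.5 at baseline and between 15.3 and 51.7 after TAB, with replicate 3 of the banded JP2NT-OE group at 15.3. The 20 most abundant transcripts took 42.0% ± 1.33 of the counts in control baseline and 34.5% ± 0.521 in control TAB libraries (SD, n = 3). Their share was 41.3% ± 0.986 in JP2NT-OE baseline and 38.3% ± 1.0 in JP2NT-OE TAB libraries. Banded and baseline libraries did not overlap in this share in either genotype (exact two-sided permutation p = 0.1 for each, the smallest that 3 libraries against 3 allow). Nor did the banded libraries of the 2 genotypes, with a share higher by 3.83 percentage points in JP2NT-OE (exact two-sided permutation p = 0.1).

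**Figure D1:**
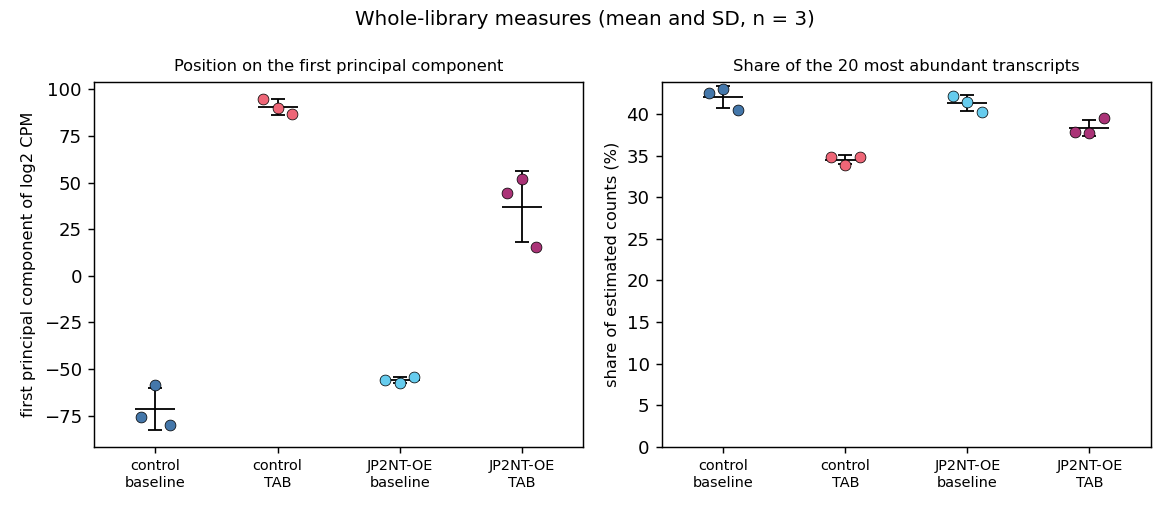
Position of each library on the first principal component of log2 CPM (left) and share of the estimated counts, in percent, taken by the 20 most abundant transcripts (right), for the 4 groups. Points are libraries and bars are the mean and SD (n = 3). The banded JP2NT-OE libraries, at 15.3 to 51.7, lie between the baseline libraries and the banded controls at 86.6 to 94.9.

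The comparison of banded with baseline control hearts asked what differed 3 weeks after the operation without the transgene. Banding changed 3722 of 43256 transcripts (8.60%), of which 1798 rose and 1924 fell. Rises of at least 1 on the log2 scale were found for 705 transcripts and falls of that size for 454. ENSMUST00000190535.6 rose from 0.0812 ± 0.141 CPM at baseline to 44.4 ± 3.37 CPM after TAB (SD, n = 3), a log2 fold change of 8.99 (SE 0.996, edgeR adjusted p = 0.000685). Its baseline value rested on 10.5 estimated counts, of which 10.4 were in control baseline replicate 1, and the other 2 libraries were at 0 CPM. The size of this fold is therefore not determined: without that replicate the fitted log2 value was 13.9, and over the alternatives it ran from 3.91 to 13.9. The 3.91 is a difference of log2(TPM + 1), in which the added 1 shrinks the folds of transcripts at low TPM. ENSMUST00000110084.2 fell from 33.1 ± 11.9 to 0.758 ± 0.643 CPM, a log2 fold change of -5.43 (SE 1.08, edgeR adjusted p = 0.0119). ENSMUST00000034172.7 fell from 60.6 ± 9.51 to 3.87 ± 0.940 CPM, a log2 fold change of -3.97 (SE 0.25, edgeR adjusted p = 0.000149).

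Calls were more frequent among abundant transcripts, where detection was also better. When the tested transcripts were ordered by mean abundance and divided into 3 parts of equal size, banding in controls changed 19.4% of the most abundant part, 4.99% of the middle part and 1.39% of the least abundant part. In simulated data for this comparison, with fewer changed transcripts, 85.7% of 2-fold changes were recovered at 5 CPM or more (18 of 21) and 26.9% over all abundances. The shares by abundance therefore do not show that abundant transcripts responded more often. Falls outnumbered rises in the most abundant part (1561 against 1241), and rises outnumbered falls in the least abundant part (133 against 68). By length, 5.52% of transcripts up to 1220 bases and 10.5% of those from 2978 bases were changed, shares that were not tested against each other.

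The balance of rises and falls rested on the scaling of the libraries. TMM factors placed the median transcript at a log2 fold change of 0.01, so that every direction is relative to it. With library totals alone, the median transcript stood at 0.19, and 3895 transcripts rose and 919 fell. With limma on log2(TPM + 1), 7685 rose and 702 fell. ENSMUST00000190535.6 rose, and ENSMUST00000110084.2 and ENSMUST00000034172.7 fell, under both of these scalings too. DESeq2 called 5709 transcripts, 3675 of them among the 3722, while fits without control baseline replicate 1, control baseline replicate 3 or control TAB replicate 2 called 2231, 2266 and 2442.

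The same operation in JP2NT-OE hearts asked how the ventricle with the transgene responded. Banding changed 103 transcripts, of which 46 rose and 57 fell, and 5197 had an unadjusted p under 0.05 compared with 9530 in controls. Of the 46 rises, 39 were also rises in controls, and of the 57 falls, 53 were also falls in controls. Independent lists of these sizes would share 1.91 and 2.54 transcripts, the 2 comparisons share no library, and 0 transcripts were called in opposite directions. The 2 largest rises and 2 largest falls under the rule for named items had log2 fold changes of 3.19, 2.77, -1.76 and -1.72 (edgeR adjusted p = 0.0387 for each). In controls, where they were not selected, these were 4.72, 4.72, -0.40 and -1.61. The transcripts named next were taken by the rule for other comparisons. ENSMUST00000034172.7 stood at 52.2 ± 7.0 CPM at baseline and 39.3 ± 11.2 CPM after TAB in JP2NT-OE, a log2 fold change of -0.41 that did not pass (SE 0.22, edgeR adjusted p = 0.511). ENSMUST00000190535.6 stood at 10.7 ± 8.18 and 28.2 ± 4.73 CPM (log2 fold change 1.40, SE 0.59, edgeR adjusted p = 0.377). That log2 fold change ran from 0.914 to 2.04 over the alternatives, with the highest value without JP2NT-OE baseline replicate 1. ENSMUST00000110084.2 stood at 12.9 ± 7.60 and 1.05 ± 1.37 CPM (log2 fold change -3.56, SE 0.995, edgeR adjusted p = 0.163), and passed only with limma on log2(TPM + 1). Its size is uncertain: the log2 fold change was -5.54 without JP2NT-OE TAB replicate 1 and ran from -5.54 to -1.62 over the alternatives. The -1.62 is a difference of log2(TPM + 1), shrunk by the added 1, and not a like estimate of the fold.

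Most transcripts changed by banding in controls had a fold change of the same sign in JP2NT-OE. Of the 1798 that rose in controls, 1638 (91.1%) had a positive fold change in JP2NT-OE, and of the 1924 that fell, 1764 (91.7%) had a negative one. Their median log2 fold changes were 0.31 and -0.23 in JP2NT-OE and 0.81 and -0.58 in controls, where they had been selected. The 46 transcripts called as rises in JP2NT-OE had a median of 0.76 in both genotypes, and the 57 called as falls had -0.61 in JP2NT-OE, where they had been selected, and -0.76 in controls. Across all tested transcripts, which are not independent replicates, the log2 fold changes of the 2 genotypes had a Pearson correlation of 0.194 and a Spearman correlation of 0.315. Among transcripts with a mean of at least 1 on the log2 CPM scale, Pearson's correlation was 0.554. The count of 103 was fragile: without JP2NT-OE baseline replicates 1, 2 and 3 in turn it was 26, 3 and 12, and without JP2NT-OE TAB replicates 1, 2 and 3 it was 8, 4 and 407. DESeq2 called 1697 transcripts, a fit of these 6 libraries alone called 4, and with library totals alone 156 rose and 39 fell.

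The comparison of genotypes at baseline asked what differed between them in unoperated hearts. It called 3 transcripts, which were all higher in JP2NT-OE, and 1897 had an unadjusted p under 0.05. That is a share under 0.05 of the 43256 tested, fewer than would be reached with no effect at all. Whether any of the 3 belongs to the transgene's own gene was not checked, so a call may reflect reads from the construct itself. ENSMUST00000017961.10 was at 740 ± 50.6 CPM in JP2NT-OE and 398 ± 25.7 CPM in control hearts (SD, n = 3), a log2 fold change of 0.89 (SE 0.10, edgeR adjusted p = 0.0428). The other 2 had log2 fold changes of 8.29 (SE 0.71) and 4.84 (SE 0.49), each with an edgeR adjusted p of 0.0422, at mean abundances of -0.77 and 0.84 on the log2 CPM scale, below the minimum set for named items, and are given here because they were seen to pass. ENSMUST00000190535.6 stood at 10.7 ± 8.18 CPM in JP2NT-OE and 0.0812 ± 0.141 CPM in control hearts, and did not pass (log2 fold change 6.93, SE 1.01, edgeR adjusted p = 0.167), although it passed with DESeq2 and without JP2NT-OE baseline replicate 3 (edgeR adjusted p = 0.00621, with a range of 1.6e-06 to 0.645 over the alternatives). Its fitted log2 fold change was 11.9 without control baseline replicate 1 and ran from 1.68 to 11.9 over the alternatives, where 1.68 is a difference of log2(TPM + 1), shrunk by the added 1. The call of ENSMUST00000017961.10 was lost in fits without any 1 of the 6 baseline libraries, where its log2 fold change stayed between 0.84 and 0.94. DESeq2 called 127 transcripts, 84 higher and 43 lower. Fits without control baseline replicates 1, 2 and 3 in turn, or without JP2NT-OE baseline replicate 2, called 0 (edgeR, 1759, 2476, 1923 and 1806 with an unadjusted p under 0.05), and those without JP2NT-OE baseline replicates 1 and 3 called 7 (2 higher, 5 lower) and 8 (4 higher, 4 lower), so the single direction of the 3 calls did not hold there. The 1759 and 1923 were again under a share of 0.05 of the transcripts tested, and the 2476 was over it.

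The comparison of genotypes after TAB asked how the banded ventricles differed. Of 195 changed transcripts, 138 were higher and 57 were lower in JP2NT-OE. ENSMUST00000034172.7 was at 39.3 ± 11.2 CPM in banded JP2NT-OE and 3.87 ± 0.940 CPM in banded control hearts, a log2 fold change of 3.34 (SE 0.25, edgeR adjusted p = 0.00292). ENSMUST00000017961.10 was at 596 ± 63.9 and 381 ± 40.8 CPM, a log2 fold change of 0.65 (SE 0.10, edgeR adjusted p = 0.0295), a call that was lost without control TAB replicate 1 or 2 or any 1 banded JP2NT-OE library. It was 1 of 2 transcripts called at baseline that were called again after TAB. As at baseline, whether it belongs to the transgene's own gene was not checked, so the call may reflect reads from the construct. Of the 138 that were higher, 68 (49.3%) had a fold change of the same sign at baseline, 12 of them with an unadjusted p under 0.05. Of the 57 that were lower, 10 (17.5%) had the same sign at baseline, 1 of them with an unadjusted p under 0.05.

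The transcripts that differed between genotypes after TAB were largely those that banding changed in controls, with the opposite sign. Of the 138 that were higher in banded JP2NT-OE, 122 had fallen with banding in controls, and of the 57 that were lower, 55 had risen. Independent lists would share 6.14 and 2.37. Both comparisons use the banded control libraries, so the sharing can add to this overlap. By how much was not measured, since the simulations that follow called 0 transcripts in either comparison. In 10 simulations with no effect at all, the correlation of the log2 fold changes was -0.50 on average, and the observed correlation was -0.50. These simulations gave all 4 groups the same mean, without a response to banding, which by itself sets the correlation near -0.50. The match therefore does not show that the sharing accounts for the observed correlation. Among transcripts with a mean of at least 1 on the log2 CPM scale, the observed correlation was -0.67, outside the simulated range of -0.53 to -0.48 for the same transcripts. The covariance was -0.584 against a simulated -0.467, a difference of -0.116. The excess of transcripts that were higher in JP2NT-OE also rested on the scaling: with library totals alone 51 were higher and 79 lower, and with limma on log2(TPM + 1) 51 were higher and 365 lower. Fits without control TAB replicates 1, 2 and 3 called 29, 16 and 101 transcripts, and fits without JP2NT-OE TAB replicates 1, 2 and 3 called 55, 22 and 39. DESeq2 called 1459, and edgeR on these 6 libraries alone called 0 (3875 with an unadjusted p under 0.05).

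The interaction asked directly whether banding acted differently in the 2 genotypes. It called 1 transcript, ENSMUST00000034172.7, whose log2 banding effect was higher by 3.56 in JP2NT-OE than in controls (SE 0.32, edgeR adjusted p = 0.0231). The fold changes that enter it are -3.97 in controls and -0.41 in JP2NT-OE, and the lowest banded JP2NT-OE library, at 32.5 CPM, stood above the highest banded control library, at 4.63 CPM. In all, 3741 transcripts had an unadjusted p under 0.05. The call of ENSMUST00000034172.7 was lost without control baseline replicate 1 or 3, JP2NT-OE baseline replicate 2 or 3, or control TAB replicate 1 or 2, where the log2 difference stayed between 3.47 and 3.71. The number of calls was 0 without control baseline replicate 3, JP2NT-OE baseline replicate 2 or control TAB replicate 1 (edgeR, 3487, 3548 and 3961 with an unadjusted p under 0.05), and between 2 and 8 without JP2NT-OE baseline replicate 1 or 3, control TAB replicate 3 or any 1 banded JP2NT-OE library. DESeq2 called 714 transcripts, with 351 positive and 363 negative differences.

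**Figure D2:**
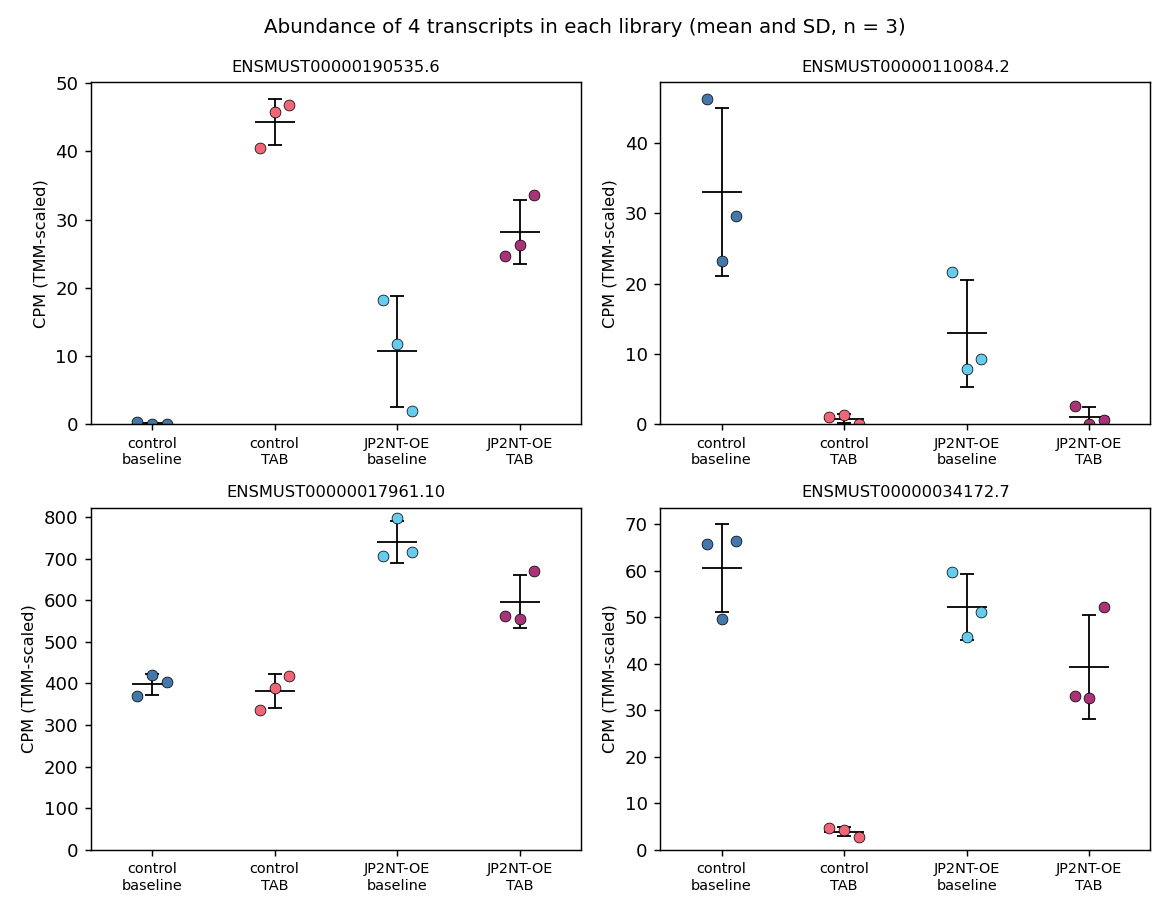
TMM-scaled CPM of 4 transcripts in each library of the 4 groups; points are libraries, bars are the mean and SD (n = 3), and each vertical axis starts at 0. ENSMUST00000034172.7 falls from 60.6 to 3.87 CPM with banding in controls and stands at 39.3 CPM in banded JP2NT-OE hearts, while ENSMUST00000017961.10 is at 740 CPM in JP2NT-OE and 398 CPM in control hearts at baseline.

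Over transcripts as a whole, the response to banding was smaller in JP2NT-OE hearts. Freed of the spread between libraries, the SD of the log2 banding effect was 0.457 in controls and 0.267 in JP2NT-OE, a ratio of 0.584 (jackknife SE 0.127, exact two-sided permutation p = 0.01 over 400 assignments). The ratio stayed between 0.532 and 0.673 when each library was left out. By the same products, the slope across transcripts on the control response was 0.508 for the JP2NT-OE response (0.469 to 0.578 without 1 library). It was -0.379 for the genotype difference after TAB (-0.419 to -0.310). With no difference at baseline along that response, the sizes of these slopes would add to 1. They add to less, so a part of the smaller response may lie at baseline, which was not tested. The banding effects of the 2 genotypes had a correlation of 0.870 after the same correction (jackknife SE 0.102, range 0.802 to 0.915 without 1 library). By the same measure, genotypes differed with an SD of 0.0795 at baseline and 0.203 after TAB (0.175 to 0.216 without 1 library). The baseline value is poorly determined: it was 0 without control baseline replicate 1 or JP2NT-OE baseline replicate 2, 0.0529 without control baseline replicate 3, 0.131 without control baseline replicate 2 and 0.129 without JP2NT-OE baseline replicate 3, and 0 with whole counts only. The 500 transcripts ranked first as rising in 4 control libraries had a median log2 change of 0.89 in the control libraries left out (range 0.66 to 0.98 over 9 choices) and of 0.42 in JP2NT-OE (0.40 to 0.43). The 500 ranked first as falling had medians of -0.64 (-0.70 to -0.61) and -0.32 (-0.33 to -0.30). Selection in controls by itself favours a larger change in controls, so the ranking was also made in 4 JP2NT-OE libraries. The 500 then ranked as rising had a median of 0.39 in the JP2NT-OE libraries left out (0.26 to 0.48) and 0.52 in controls (0.50 to 0.76), and the 500 ranked as falling had medians of -0.37 (-0.41 to -0.19) and -0.54 (-0.55 to -0.46). In that ranking the ratio of JP2NT-OE to control was 0.36 to 0.43 for rises and 0.34 to 0.46 for falls in the 3 choices that left out replicate 3 of the banded JP2NT-OE group and read the change in it, and 0.63 to 0.93 and 0.69 to 0.78 in the other 6. The median change was smaller in JP2NT-OE in all 9 choices, for both directions and under both rankings, but the choices reuse the same libraries and are not independent.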

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

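The estimate of response size and the thinning of libraries were chosen after the numbers of calls had been seen, and the other tests below were set out before their results were known. The interaction test singled out ENSMUST00000034172.7, whose log2 banding effect was higher by 3.56 in JP2NT-OE than in controls. The permutation of genotype singled out the size of the banding response, which was 0.584 of that in controls.

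Banding changed 103 transcripts in JP2NT-OE and 3722 in controls. The size of this contrast depended on the tool and the filter. DESeq2 gave 1697 and 5709, and the filter of at least 1 CPM in 3 libraries gave 372 and 4307. Whole counts only gave 102 and 783 of 2474 tested. Unequal depth is argued against: with every library thinned to the total of the shallowest, controls still had 27.0 times as many changed transcripts. A larger spread between JP2NT-OE libraries as the whole cause is argued against by the ratio of 0.584 (jackknife SE 0.127), to which that spread does not add. The exact two-sided permutation p of 0.01 behind this ratio comes from exchanging genotypes, which takes their spread as equal. That p therefore cannot decide on unequal spread. Both counts also came from 1 fit with a shared estimate of the spread per transcript, so a larger spread in JP2NT-OE would enter both. Milder banding in the JP2NT-OE mice stays open and cannot be told apart from a weaker response to the same load, since no measure of the load was used here and the corrected correlation of 0.870 (jackknife SE 0.102, range 0.802 to 0.915 without 1 library) does not decide it: it lies below the value of 1 that a strictly uniform shrinkage gives, by 1 to 2 SE, and above the bound of 0.5 set beforehand. In simulated data with a uniform ratio of 0.5, that correlation was 1.01. An effect of the transgene on the response is a hypothesis that may hold beside milder banding, and replicate 3 of the banded JP2NT-OE group, without which the ratio was 0.673 and the number of changed transcripts 407, shows how far 1 library can move both values. Milder banding would not move unoperated hearts, so it leaves any part that lies at baseline unexplained. Baseline JP2NT-OE libraries lay at -57.7 to -54.5 on the first principal component, nearer the banded libraries than baseline controls at -80.0 to -58.4.

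The genotype difference after TAB ran opposite to the banding response of controls. The sharing of banded control libraries as the whole cause is argued against: with products taken only between separate libraries, the covariance of both differences was -0.0793, and it stayed below 0 when each library was left out, with a highest value of -0.0647. A smaller response of JP2NT-OE gives the same opposition, so this is not separate evidence for it. The covariance does not separate an effect of the transgene from a lighter load.

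Other splits of the libraries were tried for each number of changed transcripts. The 6 libraries of each comparison between groups allow 10 splits, too few for a share under 0.05. Banding in controls gave 3722 in the real split and at most 3 in the others, so that 1 split of 10 reached it. Banding in JP2NT-OE gave 103 against at most 3 (1 split of 10), genotype at baseline 3 against at most 3 (2 splits of 10), and genotype after TAB 195 against at most 4 (1 split of 10). For the interaction, 27 of 100 splits gave at least the 1 call of the real one and the highest of the others gave 8, so chance cannot be excluded for that count.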

How the results depend on the processing

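Library totals without TMM factors, the 20 most abundant transcripts left out, whole counts only, thinning, and all settings of the response ratio were chosen after seeing the data. The numbers of calls, in the order banding in controls, banding in JP2NT-OE, genotype at baseline, genotype after TAB and interaction, were as follows. DESeq2 gave 5709, 1697, 127, 1459 and 714. Fits of only the groups compared gave 2401, 4, 1 and 0 for the first 4. With limma, log2(TPM + 1) gave 8387, 536, 3, 416 and 10, and log2(TPM + 0.1) gave 7903, 591, 7, 235 and 11. Without a filter, banding in JP2NT-OE gave 33 and genotype after TAB 98. With at least 1 CPM in 3 libraries, which tested 26982 transcripts, they gave 372 and 369, and the interaction 7. Library totals alone gave 195 for banding in JP2NT-OE. Whole counts only, with 2474 transcripts tested instead of 43256, gave 783, 102, 0 (80 with an unadjusted p under 0.05), 117 and 5. Relative to the number tested, calls for both banding comparisons and for genotype after TAB were more frequent there. Leaving out the 20 most abundant gave 4 for the interaction. RLE factors, length offsets and thinning left all 5 numbers within 1.5 times. Leaving out 1 library gave 2231 to 2970, 3 to 407, 0 to 8, 16 to 101 and 0 to 8, from fewer libraries. Otherwise the cause was not tested.

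With the replicate number as a block, edgeR gave 3040, 0, 0, 15 and 0 calls, with 4817, 1677 and 3448 at an unadjusted p under 0.05 for the 3 counts of 0. The 1677, for genotype at baseline, is a share under 0.05 of the 43256 tested. No pairing by number was seen: the 18 same-numbered pairs of different groups correlated between -0.0933 and 0.0863 in their deviations, and 4 of 12 libraries were closest to their own number. A weak pairing might not show in deviations from means of 3 libraries, so it is not excluded.

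The correlation of the banding effects, 0.194, was 0.316 with the stricter filter and 0.121 to 0.164 without 1 library. The response ratio stayed between 0.562 and 0.636 under other filters. Of the values of the 4 named transcripts under these settings, 351 kept their direction and side of the threshold or had no call to lose, 23 lost a call, 6 gained one and none with a call changed sign. The alternative without mitochondrially encoded genes and the settings for gene lists were not run. In simulated data for banding in controls, with 200 transcripts changed, 39.4% of 4-fold changes were recovered over all abundances and 82.4% at 5 CPM or more (14 of 17).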

Other observations

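More transcripts had an estimated count above 0 in banded hearts. The number ran from 56066 to 57003 in control baseline and from 58335 to 58692 in control TAB libraries. In JP2NT-OE it ran from 56864 to 57505 at baseline and from 57725 to 59547 after TAB, where the highest value belongs to the deepest library of the series, at 53097801 counts. The median difference between annotated and effective length, a measure of fragment length, was 163.3 ± 0.966 bases in control baseline, 166.7 ± 0.287 in control TAB, 162.0 ± 1.43 in JP2NT-OE baseline and 165.4 ± 0.784 in JP2NT-OE TAB libraries (SD, n = 3). Banded libraries were longer in both genotypes without overlap (exact two-sided permutation p = 0.1 for each, the smallest possible). Banded JP2NT-OE libraries, at 164.5 to 166.0 bases, were also shorter than banded control libraries, at 166.4 to 167.0, by 1.40 bases (exact two-sided permutation p = 0.1). Fragment length thus moved with the genotype difference after TAB. Effective-length offsets left the number of changed transcripts there at 195, but so small a difference alters the offsets of most transcripts little. This does not test whether what set the fragment lengths apart also moved the calls.

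Of the transcripts that banding changed in controls, 32 had a mean under 0.1 CPM in 1 control group and over 1 CPM in the other, among them ENSMUST00000190535.6 at 0.0812 and 44.4 CPM. Of these, 25 rose and 7 fell. A candidate explanation is the division of reads among similar transcripts, which could move reads from one transcript of a gene to another. Whole counts in all 12 libraries, which such transcripts should lack, were found for 2 of the 32 (6.25%) and for 431 of the 3507 other changed transcripts over 1 CPM (12.3%; Fisher's exact two-sided p = 0.42). The 32 transcripts are too few to decide it, and no biological explanation was tested.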
